A study of Mus musculus with 3 samples.

How the data were processed

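The series measured the transcriptome of 1 sorted population from mouse lymph nodes by bulk RNA sequencing. Per the labels, B16F10 cells, a melanoma line derived from C57BL/6 mice, were implanted in C57BL/6 mice. The tumours grew for 14 days without treatment, and the nodes draining them were pooled and disaggregated. Cells positive for Ly6C and c-kit and negative for CD11c were then sorted. Libraries were made from 8 ng of total RNA with a stranded total RNA kit for very low inputs, per the labels' protocols. Such a kit captures nascent, nuclear and noncoding RNA as well as polyadenylated messengers, so levels here are levels of total RNA.

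The deposited table holds whole-number read counts for 17857 genes in 3 libraries, 1 column per library, with an Entrez identifier and a gene length in bases for each gene. The submitters' processing notes list bcl2fastq, STAR 2.75, featureCounts and DESeq2 1.18.1 with the mouse build mm10. They give no role for each tool. The annotation release, the strand setting of the counting, the treatment of reads with several matches and any filter on genes were not given in the sources used here. A gene and an antisense partner that overlap it may therefore share reads. So may close paralogs, among them Ly6c1 and Ly6c2, Hba-a1 and Hba-a2, Trbc1 and Trbc2, Hspa1a and Hspa1b, and the replication histones, and their split is uncertain. The counts as deposited were used with no change. Of the gene symbols, 25 had the form of calendar dates and were restored through their Entrez identifiers. Identifiers of 17795 genes matched the RefSeq genes of GRCm38.p6, the assembly that mm10 represents, and 17038 were protein coding there. Gene coordinates come from that table, count from 1 and cover the whole gene, exons and introns together.

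The labels give 1 group of 3 libraries and no control population, so no comparison between groups could be made. The design text mentions public data on conventional type 1 dendritic cells, which were not analysed here. The libraries are labelled as 3 repeat experiments on pooled nodes. The number of mice per pool was not given in the sources used here, and p-values measure only the spread between these 3 samples, which may be technical.

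Totals were 9077195, 13885509 and 13861430 counts in replicates 1, 2 and 3. Normalised read counts (CPM) were computed in edgeR 4.0.16 with TMM factors of 1.04, 1.01 and 0.950. A count of 0 allows up to 3 counts, which is 0.317, 0.214 and 0.228 CPM in replicates 1, 2 and 3. Intervals for shares of counts are 95% Wilson intervals. Reads carry no molecular identifier in the table, so intervals and limits cover counting error only. CPM is not scaled by gene length, so it ranks long genes above short ones with as many transcripts.

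Genes with a sum of at least 10 counts were tested, 15490 in all. The other 2367 were not. For each gene, edgeR's quasi-likelihood test asked whether its level differed from 1 CPM and, separately, from 50 CPM. The design had an intercept alone, the reference level entered through the offsets, and the tests were two-sided. P-values were adjusted by Benjamini and Hochberg's method over the genes tested, with a threshold of 0.05. Unless said otherwise, adjusted p denotes this test. For lists of genes, the count of calls is also given with p-values adjusted over the list alone where it differs.

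In tests on simulated data drawn from the means and totals of these libraries, 200 genes were set apart from the reference. Against 1 CPM, with 14269 genes tested, the test found 24% of genes placed 2-fold above it, 80% at 4-fold, 96% at 8-fold and 100% at 16-fold. It found 0% of the genes placed below 1 CPM, so an absence of calls below 1 CPM in this test is no evidence that levels lie at or above it. It called 2% of the genes placed at the reference. Against 50 CPM, with 14361 genes tested, it found 100% of the genes placed 2-fold to 16-fold above or below and called 7.5% of the genes placed at 50 CPM. That rate does not carry over to real genes that were uneven between libraries. Camp, with a mean of 13.4 CPM (adjusted p = 0.0875), and Ido2, with 0.458 CPM (0.0542), were not separated from 50 CPM. A gene not separated from 50 CPM therefore need not lie within 2-fold of it.

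Before the data were examined, 34 gene lists were fixed, 21 of them for cell types, together with the tests and a rule for the genes named. The lists hold 341 different genes, of which 331 were measured, and 6 genes stand in more than 1 list. Klra8, Il17a, Mcpt4, Mcpt8, Prss34, Mrgprb2, Hbb-bt, Tyr, Ddx3y and Eif2s3y were not analysed here. The rule names the 20 genes with the highest mean CPM outside mitochondrial, ribosomal protein and nuclear noncoding genes. It names the 2 highest and 2 lowest measured members of each list, all sort markers, all genes of the BTK, IDO and mTOR list and of the transcription factor list, and Trp53, Mdm2, Cdkn1a, Flt3, Csf1r, Ccr2, Itgae, H2-Ab1, Cd74 and Mki67. It also names the 10 genes with the largest SD of log2 CPM between libraries among those with a mean of at least 10 CPM. Any other gene named was chosen after its values were seen. A further 9 lists were written after the fixed lists had been examined and are used only in the closing section.

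Marker lists were compared within each library as the difference of their mean log2 CPM with a prior count of 2. The 6 differences were tested over libraries by an exact two-sided sign-flip permutation test, whose smallest possible p with 3 libraries is 0.25. No list difference can thus pass a threshold of 0.05, and the per-library values carry the comparison. The spread between libraries was summarised by edgeR's common biological coefficient of variation.

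As a measure of background, CPM per kilobase were taken over 578 olfactory receptor genes, which leukocytes are not known to use widely. A gene was called over background in a library when it exceeded the 99th percentile of these genes there. Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma 3.58.1 with a trend, library totals without scaling and other filters on low counts. The others were leaving out noncoding, ribosomal protein and mitochondrial genes, prior counts of 0.5 and 5, the median over a list, counts per kilobase, and leaving out each library in turn. The background rule and edgeR's robust empirical Bayes were added after seeing the data. Computations used R 4.3.3, and plots used Python 3.11.15 with matplotlib 3.10.9.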

Results

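RNA was sequenced from leukocytes sorted from the lymph nodes that drained B16F10 melanomas in mice, 14 days after the tumours were implanted and without treatment. The sort took cells that displayed Ly6C, a surface protein of monocytes and of some lymphocytes, and c-kit, the receptor for stem cell factor, and that lacked CD11c, the integrin chain that marks most dendritic cells. The 3 libraries form 1 group and come from 3 repeat experiments, called replicates 1, 2 and 3 here. The series' title names the kinase BTK and the tryptophan-degrading enzyme IDO as controls on how inflammatory dendritic cells mature in tumours. The question put to these libraries was which lineage programmes and which genes of that pathway the sorted cells carried. Levels are given in normalised read counts (CPM) as mean ± SD over the 3 libraries (n = 3) unless stated otherwise.

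The libraries held 9077195, 13885509 and 13861430 counts. Mitochondrial ribosomal RNA took 17.8% of counts in replicate 1 (95% Wilson interval 17.7 to 17.8%), 6.22% in replicate 2 (6.21 to 6.23%) and 13.1% in replicate 3 (13.1 to 13.1%). Malat1, a long noncoding RNA retained in the nucleus, took 2.746%, 3.46% and 3.93% (intervals 2.74 to 2.76%, 3.45 to 3.47% and 3.92 to 3.94%). Of the 17857 genes, 632, 3788 and 2199 had no count in replicates 1, 2 and 3. Olfactory receptor genes averaged 0.255, 0.0224 and 0.0525 CPM per kilobase of gene, so the shallowest library, replicate 1, carried the most counts over genes that leukocytes rarely use. Across the 15490 genes tested, which are not independent replicates, Pearson's r of log2 CPM was 0.917 between replicates 1 and 2, 0.941 between 1 and 3, and 0.961 between 2 and 3. In a check for duplicate libraries, no pair agreed within sampling noise, with chi-square values of 115, 42.1 and 58.9 per degree of freedom.

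Kit, the gene for c-kit, was read at 9.83, 5.35 and 5.93 CPM in replicates 1, 2 and 3 (7.04 ± 2.44 CPM), the 41.9th percentile of the genes tested by mean level. Ly6c1 was read at 19.1, 4.28 and 17.6 CPM and Ly6c2 at 11.5, 121 and 41.3 CPM. Itgax, which encodes the CD11c that the sort excluded, was read at 26.95, 43.2 and 24.01 CPM, above Kit in each of the 3 libraries. All 4 genes lay above 1 CPM in edgeR's test, and Kit (adjusted p = 5.59e-04), Ly6c1 (0.00651) and Itgax (0.02297) lay below 50 CPM, while Ly6c2 was not separated from it (0.672). Without replicate 1 or without replicate 3, Itgax no longer passed against 50 CPM. In the mm10 build the genes span Entrez gene 16590, chromosome 5, 75574987 to 75656722 (Kit), Entrez gene 17067, chromosome 15, 75044018 to 75048920 (Ly6c1), Entrez gene 100041546, chromosome 15, 75108161 to 75112066 (Ly6c2) and Entrez gene 16411, chromosome 7, 128129526 to 128150657 (Itgax). Because these genes or their products defined the sort, their levels serve as a check on the gate and do not name a lineage. In that check the gene of the excluded marker, Itgax, stood above the gene of a required one, Kit. Surface protein was not measured in these libraries, so the check does not settle whether the sort was clean.

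Outside mitochondrial, ribosomal protein and nuclear noncoding genes, Macf1, a crosslinker of actin and microtubules, had the highest mean level, with 5958 ± 1593 CPM, followed by Actb (5413 ± 267), which encodes beta-actin, Myh9 (4488 ± 1434), a nonmuscle myosin, and Ptprc (2743 ± 383), which encodes the leukocyte antigen CD45. Next came the translation elongation factors Eef1a1 (2255 ± 221) and Eef2 (2244 ± 592), the X-inactivation RNA Xist (2249 ± 293), Utrn (2222 ± 562), Ahnak (2102 ± 1568) and Dock2 (1953 ± 480.2), a guanine nucleotide exchange factor of leukocytes. Kmt2d, Srrm2, Akap13, Prrc2c, H2-K1, Ddx5, Plec, Flna, Ets1 and Hsp90ab1 completed the first 20, from 1827 for Kmt2d to 1455 CPM for Hsp90ab1. Ahnak was uneven, with 870.3, 3868 and 1569.5 CPM in replicates 1, 2 and 3.

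In edgeR's test, 10623 of 15490 genes lay above 1 CPM, and 9646 of these also exceeded the olfactory receptor background in all 3 libraries. No gene was called below 1 CPM by edgeR, DESeq2 or limma, and 0 were below it at an unadjusted p under 0.05 in edgeR. Of the 42 olfactory receptor genes with enough counts to test, 0 were called above 1 CPM by edgeR, DESeq2 or limma, or at an unadjusted p under 0.05. Against 50 CPM, 3084 genes lay above and 10335 below, and 2071 were not separated from it. Without replicate 3 the number below 50 CPM was 5494, and with edgeR's own expression filter it was 6184.

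T cell genes stood highest of the 21 cell type lists in every library by mean log2 CPM. In replicate 1 the erythroid list lay close (7.51 against 7.70), and its median member was read at a higher level there (386 against 316 CPM). CPM is not scaled by gene length, and the globin genes of the erythroid list are short. Hba-a1 has 559 bases and Hbb-bs 639, against 2238 for Tcf7 and 3210 for Il7r in the T cell list. The order of these 2 lists in replicate 1 is thus one of CPM and may not hold per kilobase. Tcf7, a transcription factor of T cells, was read at 1003 ± 218 CPM, and Il7r, the interleukin 7 receptor, at 622 ± 156 CPM. At the lower end of the list lay Cd5 with 163 ± 21.1 and Cd3d, a chain of the T cell receptor complex, with 141 ± 24.7. All 15 members lay above 50 CPM in edgeR's test, with adjusted p = 6.74e-08 for Tcf7 and 4.90e-05 for Cd3d. The coreceptor genes, named after their values were seen, parted between libraries. Cd8a was read at 8.67, 526 and 135 CPM, Cd8b1 at 18.2, 422 and 123 CPM and Cd4 at 482, 167 and 471 CPM in replicates 1, 2 and 3. Cd8a and Cd8b1 lay under 50 CPM in replicate 1 and were not separated from 50 CPM with robust empirical Bayes (edgeR adjusted p = 0.165 and 0.155), which left 13 members above it. Tcf7 is Entrez gene 21414, chromosome 11, 52246527 to 52283383 in mm10.

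**Figure D1:**
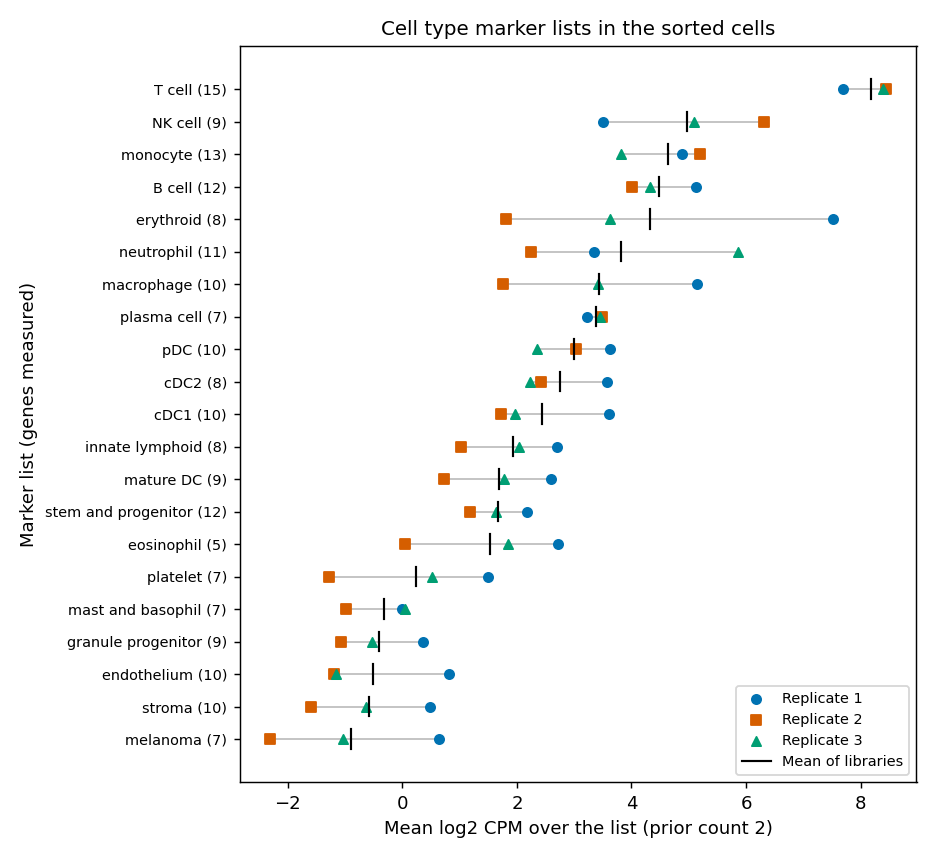
Mean log2 CPM (horizontal axis, prior count 2) over each of the 21 cell type lists (vertical axis, with the number of genes measured), 1 point per library and a bar at the mean of the 3 libraries. The T cell list lies highest at 8.17 and the melanoma list lowest at -0.90, and the erythroid, neutrophil and macrophage lists have the largest SD between libraries (2.91, 1.85 and 1.69).

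Monocyte genes were present at intermediate levels. Lyz2, the lysozyme of myeloid cells, was read at 339 ± 164 CPM, and Csf1r, the receptor for macrophage colony-stimulating factor, at 141 ± 90.9 CPM. Ccr2, the receptor that brings monocytes out of the marrow, was read at 66.8, 131 and 26.8 CPM in replicates 1, 2 and 3. Fcgr1 (7.78 ± 3.91) and Cd14 (4.07 ± 3.53) were lowest. All 13 members lay above 1 CPM (Cd14 not without replicate 1), and Lyz2 (edgeR adjusted p = 5.89e-06) and Csf1r (0.00127) lay above 50 CPM. The list's median member was 2.03 times its mean in the other libraries in replicate 2 and 0.454 times in replicate 3.

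Macrophage genes were carried mainly by replicate 1. Apoe, a lipid carrier made by macrophages, was read at 335, 63.3 and 116 CPM, and the mannose receptor gene Mrc1 at 233, 8.35 and 34.6 CPM. Vsig4 (0.878 ± 0.899) and Trem2 (0.302 ± 0.463) were at the bottom of the list. Of 10 members, 8 lay above 1 CPM and 9 were highest in replicate 1, where the median member was 7.71 times its mean in the others. Apoe alone lay above 50 CPM (edgeR adjusted p = 0.00133), a call that robust empirical Bayes ended (0.0533). The list count above 50 CPM was 2 without replicate 2 and 2 without replicate 3.

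Neutrophil genes were highest in replicate 3 for all 11 members, at a median of 9.79 times their mean in the others. S100a9, a calcium-binding protein abundant in neutrophils, was read at 62.3, 17.1 and 321 CPM in replicates 1, 2 and 3, and Csf3r, the receptor for granulocyte colony-stimulating factor, at 61.8, 41.2 and 164 CPM. Retnlg was read at 8.56, 1.43 and 23.5 CPM. Ly6g, which encodes a neutrophil surface antigen, had counts in replicate 3 alone, at 2.51 CPM. Above 1 CPM lay 10 members. S100a9 and Csf3r passed against 50 CPM (edgeR adjusted p = 0.03195 and 0.0341), but 0 did when adjusted over the list alone, 0 without replicate 3, and 5 without replicate 2. Both genes lost this call with robust empirical Bayes, and S100a9 also in the DESeq2 Wald test.

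Stem and progenitor genes were low apart from Myb. Myb, a transcription factor of progenitors that lymphocytes also use, was read at 116 ± 49.7 CPM and Cdk6 at 29.4 ± 10.2. Flt3, the receptor tyrosine kinase of early and dendritic progenitors, was read at 12.5, 16.1 and 7.29 CPM. Cd34 was read at 1.06, 0 and 0.152 CPM and Mycn had counts in replicate 3 alone (0.456 CPM). Of 12 members, 6 lay above 1 CPM and 1, Myb, above 50 CPM (edgeR adjusted p = 8.92e-04). Among 9 genes of granule-forming progenitors, Gfi1 (15.5 ± 2.01 CPM) alone lay above 1 CPM. Ms4a3 was read at 1.26 ± 1.11 CPM, Prss57 had counts only in replicate 1, and Elane, the neutrophil elastase gene, was read at 0.529, 0.0713 and 0 CPM.

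Genes of conventional dendritic cells were read at low levels, with exceptions. In the type 1 list, Wdfy4, which serves cross-presentation in these cells, was read at 116 ± 36.4 CPM, Naaa at 25.4 ± 6.58 and Itgae, which encodes the integrin chain CD103, at 17.7 ± 6.05. Batf3, the transcription factor that type 1 cells require, was read at 3.59, 0.927 and 0.456 CPM, and Gcsam at 3.81, 0.285 and 0.3799 CPM. Of 10 members, 7 lay above 1 CPM, 4 without replicate 1. Wdfy4 lay above 50 CPM (edgeR adjusted p = 4.78e-04) and 8 members lay below it. Which of the sorted cells held the Wdfy4 and Itgae transcripts was not tested, so their levels alone are no sign of type 1 cells. In the type 2 list, Dtx1, a Notch pathway gene that lymphocytes also use, was read at 203 ± 53.96 CPM and Sirpa at 91.8 ± 52.8, while Clec4a4 (1.12 ± 0.677) and Mgl2 (0.645 ± 0.542) were low. Of its 8 members, 4 lay above 1 CPM and Dtx1 and Sirpa above 50 CPM. Without replicate 1, 1 member lay above 50 CPM, and Sirpa no longer passed.

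In the plasmacytoid dendritic cell list, Pacsin1 was even between libraries (67.5 ± 0.827 CPM), and Tcf4, the factor that specifies these cells, was read at 35.8 ± 10.3. Klk1 (1.32 ± 0.985) and Cox6a2 (0.939 ± 0.641) were lowest. Above 1 CPM lay 7 of 10 members. Pacsin1 passed against 50 CPM (edgeR adjusted p = 0.0172), but 0 members did without replicate 3. In the mature dendritic cell list, Ccr7, a homing receptor shared with naive T cells, was read at 148 ± 6.89 CPM and Relb at 33.1 ± 3.69. Ccl22 was read at 0.237 ± 0.346, and Il4i1 had counts in replicate 1 alone. Of 9 members, 6 lay above 1 CPM and Ccr7 above 50 CPM (edgeR adjusted p = 1.72e-05).

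Genes of other lymphocytes were read at levels that differed between lists. In the B cell list, the complement receptor gene Cr2 (68.6 ± 40.6 CPM) and Bank1 (59.2 ± 31.7) were highest and Pax5 (10.8 ± 2.32) and Fcrla (7.85 ± 5.31) lowest. All 12 members lay above 1 CPM, all 12 were highest in replicate 1, and 0 lay above 50 CPM by edgeR, DESeq2 or limma (0 at an unadjusted p under 0.05, and 2 in edgeR without replicate 2). In the plasma cell list, Jchain, which links antibody polymers, was read at 147 ± 56.3 and Xbp1 at 57.5 ± 0.954. Derl3 (2.04 ± 1.17) and Tnfrsf17 (0.886 ± 0.307) were lowest, and 5 of 7 members lay above 1 CPM and 1 above 50 CPM. In the natural killer (NK) cell list, Eomes was read at 15.9, 177 and 49.5 CPM in replicates 1, 2 and 3 and Gzma at 19.03, 121 and 59.8 CPM. Klre1 was read at 2.22, 35.1 and 18.1 CPM and Gzmb at 6.24, 24.2 and 19.7 CPM. All 9 NK members lay above 1 CPM and were highest in replicate 2, at a median of 3.81 times their mean in the others. Above 50 CPM lay 0 NK members by edgeR, DESeq2 or limma (0 at an unadjusted p under 0.05), 2 in edgeR without replicate 1 and 1 without replicate 3. In the innate lymphoid list, Gata3, which T cells share, was read at 68.6 ± 2.65 and Rora at 14.2 ± 6.94, while Il23r was at 0.956 ± 0.276 and Il22 had counts in replicate 1 alone. Of its 8 members, 4 lay above 1 CPM and Gata3 above 50 CPM, a call lost without replicate 3.

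Erythroid genes were concentrated in replicate 1. The globin genes Hbb-bs and Hba-a1 were read at 1780.0, 22.7 and 142 CPM and 1106, 13.6 and 65.6 CPM in replicates 1, 2 and 3. Klf1, the erythroid transcription factor, was read at 17.8, 1.36 and 0.608 CPM and Epor, the erythropoietin receptor, at 7.08, 0 and 1.14 CPM. All 8 members were highest in replicate 1, at a median of 29.6 times their mean in the others. In edgeR's test 7 lay above 1 CPM and 4 above 50 CPM, but 0 lay above 50 CPM without replicate 1 and 0 with robust empirical Bayes. Klf1 lost its call against 1 CPM under both. In the platelet list, Itga2b was read at 8.75 ± 4.77 and Ppbp at 3.54 ± 3.204, with Gp9 (0.514 ± 0.593) and Gp1bb (0.3801 ± 0.403) lowest. Above 1 CPM lay 3 of 7 members, 2 when adjusted over the list alone, and 1 without replicate 1.

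Mast cell, eosinophil, stromal, endothelial and melanoma genes were mostly read at low levels. In the mast cell and basophil list, Hdc was read at 5.92, 0.642 and 27.9 CPM and Cma1 at 0.846, 6.85 and 2.89 CPM, and Tpsab1 and Tpsb2 had counts in 1 library each. Above 1 CPM lay 2 of its 7 members, 1 without replicate 2 and 1 without replicate 3. In the eosinophil list, Ccr3 was read at 63.2, 2.28 and 13.3 CPM and Il5ra at 4.84 ± 1.85, Epx at 1.496 ± 2.03 and Siglecf at 1.34 ± 0.672, with 3 of 5 members above 1 CPM. Among 10 stromal genes, 0 lay above 1 CPM by edgeR, DESeq2 or limma (0 at an unadjusted p under 0.05, and 2 in edgeR without replicate 2). Pdgfra was read at 2.41 ± 2.94, Col1a2 at 2.39 ± 2.05 and Lum at 0.111 ± 0.114, and Ccl19 had no count, which allows up to 0.317, 0.214 and 0.228 CPM in replicates 1, 2 and 3. Among 10 endothelial genes, Kdr (3.25 ± 2.61) and Ptprb (2.71 ± 1.56) lay above 1 CPM, 0 when adjusted over the list alone and 0 without replicate 1, and 1 without replicate 2. Emcn had counts in replicate 1 alone and Cldn5 had none. Among 7 melanoma genes, 0 lay above 1 CPM by edgeR, DESeq2 or limma, or at an unadjusted p under 0.05. Pmel was read at 1.63 ± 1.04, Slc45a2 at 0.912 ± 1.32, Dct at 0.413 ± 0.6505 and Sox10 at 0.323 ± 0.379. In these stromal, endothelial and melanoma lists 0 members exceeded the olfactory receptor background in all 3 libraries, and all 7 melanoma genes were highest in replicate 1.

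Within each library, monocyte genes lay above those of type 1 dendritic cells, of plasmacytoid dendritic cells and of stem and progenitor cells, and below those of T cells. The monocyte list exceeded the type 1 dendritic cell list by 1.29, 3.47 and 1.86 log2 units in replicates 1, 2 and 3 (mean 2.20 ± 1.13 SD, a 4.61-fold difference). It exceeded the plasmacytoid list by 1.26, 2.16 and 1.47 (1.63 ± 0.47), and by 1.15 on average per kilobase and 0.92 with the median over list members. It exceeded the stem and progenitor list by 2.71, 4.02 and 2.19 (2.97 ± 0.94, 7.84-fold). Against the T cell list the differences were -2.81, -3.24 and -4.57 (-3.54 ± 0.92, 11.6-fold). Each of these 4 gave an exact permutation p = 0.25, the smallest that 3 libraries allow, and 0.375 after adjustment over the 6 list differences. The sign held in 3 of 3 libraries for each.

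The monocyte list did not keep 1 direction against the neutrophil and B cell lists. Against neutrophil genes the differences were 1.55, 2.95 and -2.05 (0.82 ± 2.58, exact permutation p = 0.75, adjusted 0.9), higher in 2 of 3 libraries. Against B cell genes they were -0.23, 1.19 and -0.50 (0.15 ± 0.91, exact permutation p = 1, adjusted 1), higher in 1 of 3 libraries. Both differences were smaller than the spread between libraries. Both turned negative without replicate 2 (-0.25 and -0.37) and per kilobase (-0.33 and -0.093).

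Of the genes named in the series' title, Btk was read and Ido1 barely so. Btk, a kinase of B cell and myeloid receptor signalling, was read at 27.1, 17.9 and 12.6 CPM in replicates 1, 2 and 3 (19.2 ± 7.31 CPM). Ido1, which degrades tryptophan, was read at 2.11, 0.856 and 0.532 CPM, from 20, 12 and 7 counts, and was not separated from 1 CPM (edgeR adjusted p = 0.876). Its relative Ido2 and the liver enzyme gene Tdo2 had counts in replicate 1 alone (1.37 and 0.951 CPM). Ido1 exceeded the olfactory receptor background in 1 library, replicate 2, and Ido2 and Tdo2 did in 0 libraries. The kinases upstream in receptor signalling, Syk (138 ± 6.75) and Lyn (106 ± 33.5), and the phospholipase Plcg2 (82.5 ± 28.9) lay above 50 CPM. So did Mtor (118 ± 32.2), its complex partners Rptor (112 ± 47.2) and Rictor (300.5 ± 58.3), Rps6kb1 (111 ± 17.9), Akt1 (101 ± 20.2) and Tsc1 (88.1 ± 14.7). Tsc2 was read at 66.00 ± 20.1 and was not separated from 50 CPM (edgeR adjusted p = 0.0609). The amino acid sensor Eif2ak4 (36.2 ± 2.61), Map4k3 (33.6 ± 9.14) and the aryl hydrocarbon receptor gene Ahr (14.8 ± 2.16) were read at lower levels, above 1 CPM. Of the 17 genes, 14 lay above 1 CPM and 9 above 50 CPM. Btk is Entrez gene 12229, chromosome X, 134542334 to 134583628, Ido1 Entrez gene 15930, chromosome 8, 24584133 to 24596952 and Mtor Entrez gene 56717, chromosome 4, 148448582 to 148557685 in mm10. T cells and B cells also use most genes of this list, and the levels are those of the whole sorted sample.

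Transcription factors of monocytes and dendritic cells were mostly read, and Batf3 was the exception. Zeb2 (119 ± 44.3 CPM), Id2 (97.7 ± 39.8) and Irf8 (75.5 ± 27.8), which directs monocyte and dendritic cell fates, lay above 50 CPM. For Irf8 that call (edgeR adjusted p = 0.0281) was lost without replicate 1 and without replicate 2. Nr4a1 (49.7 ± 6.92), Cebpb (47.00 ± 11.3), Irf4 (42.1 ± 10.9), Bcl6 (39.4 ± 6.39) and Tcf4 (35.8 ± 10.3) were not separated from 50 CPM. Relb (33.1 ± 3.69), Spi1 (23.3 ± 5.04), Klf4 (18.1 ± 8.22), Cebpa (12.4 ± 3.87), Nfil3 (8.604 ± 1.86) and Zbtb46 (4.31 ± 2.43), a factor of conventional dendritic cells, lay below it. For Relb the call against 50 CPM was lost without replicate 3. Batf3 (1.66 ± 1.69) was not separated from 1 CPM (edgeR adjusted p = 0.522). In all, 14 of 15 lay above 1 CPM and 3 above 50 CPM. The list was lowest in replicate 3 for 11 of 15 members. Irf8 is Entrez gene 15900, chromosome 8, 120736358 to 120756694, and Batf3 Entrez gene 381319, chromosome 1, 191098414 to 191108943 in mm10.

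**Figure D2:**
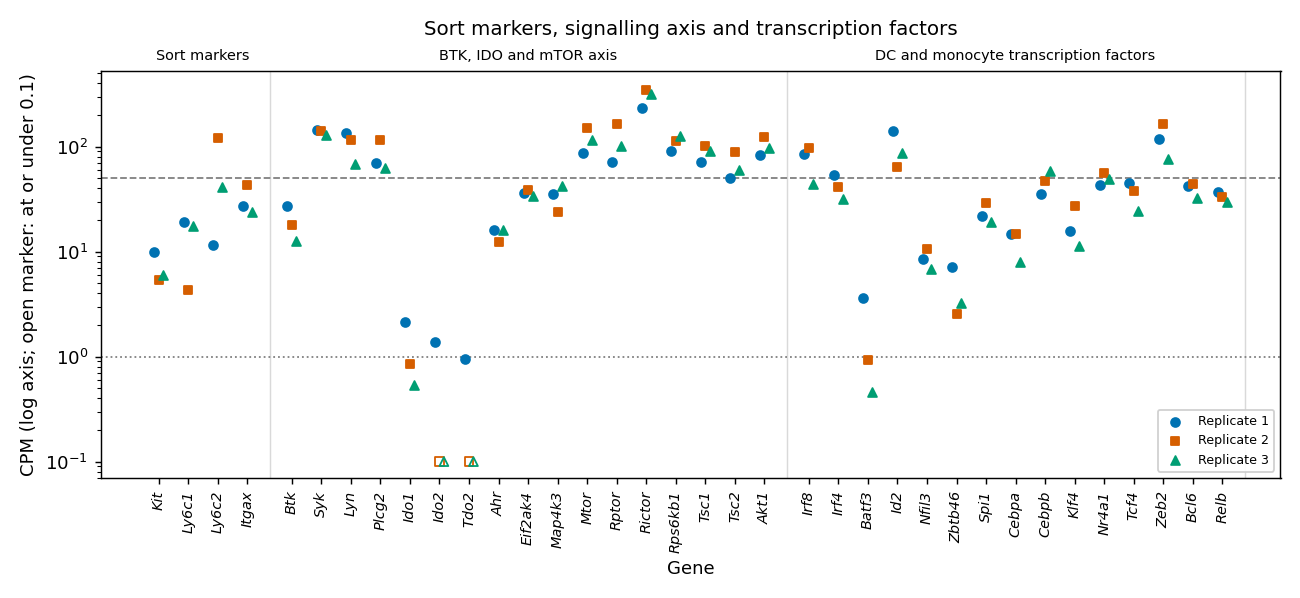
CPM on a log axis (vertical) of the sort markers, the BTK, IDO and mTOR list and the transcription factor list (horizontal), 1 point per library, with lines at 1 and 50 CPM and open markers for values at or under 0.1 CPM. Ido1, Ido2, Tdo2 and Batf3 lie near or under 1 CPM in replicates 2 and 3, and Btk lies between 12.6 and 27.1 CPM.

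Genes of antigen presentation by class II molecules were read throughout and were highest in replicate 1. Cd74, the invariant chain, was read at 633, 266 and 279.6 CPM in replicates 1, 2 and 3 and H2-Ab1 at 227, 80.97 and 92.3 CPM, while Cd40 (7.01 ± 3.65) and the costimulatory gene Cd80 (3.37 ± 2.51) were lowest. All 10 members lay above 1 CPM, 9 were highest in replicate 1, and 4 lay above 50 CPM, 2 without replicate 1 and 2 with robust empirical Bayes. Cd80 lost its call against 1 CPM without replicate 1 and without replicate 3. B cells also use these genes, and B cell genes were highest in the same library. Genes of class I processing were high and even, with H2-K1 at 1679.9 ± 208 CPM, H2-D1 at 1211 ± 134, Tap2 at 131 ± 26.7 and Psmb9 at 39.6 ± 5.74. All 10 lay above 1 CPM and 9 above 50 CPM.

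Among interferon response genes, Ifit2 was read at 103 ± 14.3 CPM, with Oas1a (7.63 ± 1.16) and the chemokine gene Cxcl10 (1.68 ± 1.33) lowest. Above 1 CPM lay 11 of 12 members and above 50 CPM 3. In the inflammatory cytokine list, Tgfb1 was read at 116 ± 27.7 and Il1b at 23.6, 5.14 and 96.2 CPM, highest in replicate 3, where neutrophil genes were also highest. Il10 (0.598 ± 0.404) and Il6 (0.227 ± 0.272) were lowest, and 4 of 12 members lay above 1 CPM, 3 when adjusted over the list alone, and 1 above 50 CPM. In the suppressive list, Vsir, which encodes the checkpoint ligand VISTA, was read at 276 ± 64.3 and Lgals9 at 75.04 ± 7.57. Arg1, the arginase of suppressive myeloid cells, was read at 1.39 ± 1.08, and Ido1 was the lowest of this list. Of 9 members, 6 lay above 1 CPM and 3 above 50 CPM.

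In the p53 list, Trp53 was read at 57.6 ± 16.4 CPM and its ubiquitin ligase gene Mdm2 at 110.1 ± 15.7. Trp53inp1 (299, 293 and 391 CPM in replicates 1, 2 and 3) and Ccng1 (162 ± 33.8) were highest. Cdkn1a, the cell cycle inhibitor p21, was read at 1.09 ± 0.232 and was not separated from 1 CPM (edgeR adjusted p = 0.924), and neither were Phlda3 (0.968 ± 0.159) and Eda2r (0.635 ± 0.693). Of 15 members, 12 lay above 1 CPM and 4 above 50 CPM.

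Proliferation genes were read in every library and were highest in replicate 1 for 14 of 17 members. Mki67, the Ki-67 antigen of cycling cells, was read at 1009, 108 and 173 CPM in replicates 1, 2 and 3, and Mcm6, a subunit of the replicative helicase, at 106, 132 and 97.6 CPM. Bub1 (3.35 ± 3.88) and Ccnb1 (3.09 ± 2.29) were lowest. The median member was 3.56 times its mean in the others in replicate 1, where erythroid genes were also highest, and replication histones took 0.382%, 0.0711% and 0.103% of counts (95% Wilson intervals 0.378 to 0.386%, 0.0697 to 0.0725% and 0.102 to 0.105%). All 17 lay above 1 CPM and 5 above 50 CPM. Without replicate 1 these counts were 14 and 3, and Bub1 and Ccnb1 were among those no longer above 1 CPM. Genes induced by tissue dissociation were led by Junb (169 ± 53.8) and Jun (115 ± 39.98), while the heat shock genes Hspa1b (3.005 ± 3.08) and Hspa1a (0.612 ± 0.361) were lowest. Of these 10, 8 lay above 1 CPM, 9 when adjusted over the list alone, and 4 above 50 CPM.

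Among sex-linked genes, Xist was read at 2249 ± 293 CPM, and the Y-linked genes Kdm5d and Uty had no count in any of the 3 libraries. In the nuclear noncoding list, Malat1 was read at 34008 ± 7507 CPM and Rpph1, the RNA of ribonuclease P, at 20320.0 ± 5189.8, with Neat1 at 495 ± 153 and Snhg11 at 1.03 ± 1.15. Of its 6 members, 5 lay above 50 CPM.

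The 10 genes that varied most between libraries were all highest in replicate 1. Hba-a1, Epb42, Hemgn, Dmtn, Aqp1 and Sox6 among them are genes of red cell precursors. Epb42 was read at 79.7, 0.785 and 4.71 CPM and Hemgn at 106, 1.14 and 5.62 CPM in replicates 1, 2 and 3. Also among the 10 were the histone gene Hist1h3c (29.3, 0 and 3.72 CPM), Apol11b (88.5, 0.499 and 6.15 CPM) and Hebp1 (26.95, 0.143 and 3.11 CPM). The biological coefficient of variation between libraries was 0.654. It was 0.355 without replicate 1 and 0.350 with edgeR's own expression filter.

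**Figure D3:**
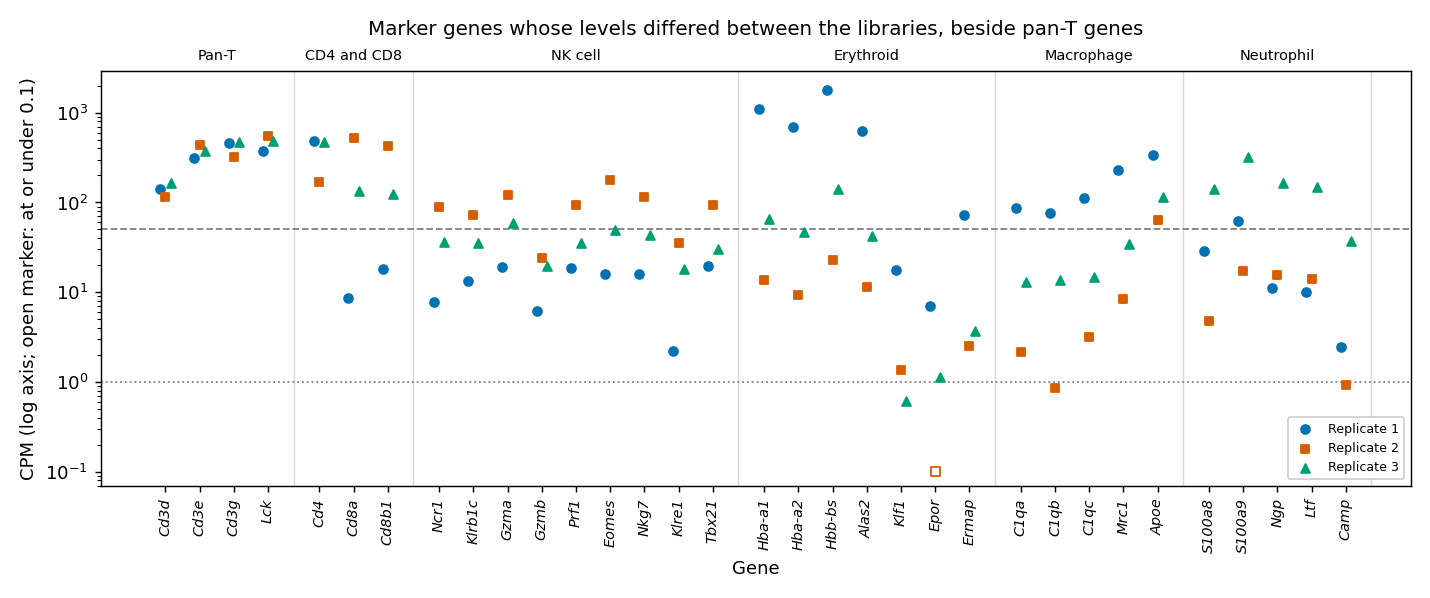
CPM on a log axis (vertical) of marker genes that differed between the libraries, beside 4 genes of all T cells (horizontal), 1 point per library, with lines at 1 and 50 CPM and an open marker for a value at or under 0.1 CPM. Cd3e stays between 316 and 439.7 CPM, whereas Cd8a is highest in replicate 2, Hbb-bs in replicate 1 and S100a9 in replicate 3.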

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

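Robust empirical Bayes and the olfactory receptor background were chosen after the data were seen, and the other alternatives before. The count of genes above 1 CPM ran from 9646 (background rule) to 10799 over all alternatives, 10281 to 10799 when 1 library was left out, and that above 50 CPM from 2745 to 3684 (2745 to 3092). The count below 50 CPM moved from 10335 to 5494 without replicate 3 and to 6184 with edgeR's expression filter, which tested 11056 genes. Left-out libraries gave 1.57 to 2.66 for the monocyte list minus the type 1 dendritic cell list, 1.36 to 1.82 for plasmacytoid, 2.45 to 3.36 for stem and progenitor and -3.91 to -3.02 for T cell genes, so these 4 differences kept their direction. The differences from neutrophil genes (-0.25 to 2.25) and B cell genes (-0.37 to 0.48) reversed without replicate 2 (-0.25 and -0.37) and per kilobase (-0.33 and -0.093). The monocyte minus plasmacytoid difference moved to 1.15 per kilobase and 0.92 with the median over list members. The coefficient of variation was 0.350 with the expression filter and 0.355 to 0.794 when 1 library was left out. Filtering drops genes of low count by construction. For the reversed and moved list differences the cause was not tested. For genes named by rule, 1905 of 2044 alternative values kept their direction and side of the threshold, 81 lost a call, 55 gained one and 3 reversed. These 3 were Klf1 against 1 CPM (-0.069 log2 without replicate 1, range -0.069 to 3.26 over left-out libraries), Hba-a1 against 50 CPM (-0.36 without replicate 1, to 3.54) and S100a9 against 50 CPM (-0.30 without replicate 3, to 1.93), each after loss of the library that held most of its counts. Lost calls came mostly without replicate 3 (40), where fewer low genes passed against 50 CPM, without replicate 1 (19) and with robust empirical Bayes (16). Depth limits what a count of 0 can exclude, levels above 0.317, 0.214 and 0.228 CPM in replicates 1, 2 and 3. The simulated test, run at 1 depth, found 0% of genes below 1 CPM. Simulated genes with a sum under 10 counts were left out of it and scored as not found, so the filter can account for part of that 0%. How large a part was not tested. No paired analysis was possible because the series has 1 group.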

Other observations

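Genes beyond the fixed lists gave further detail on the lymphocyte transcripts. Of 5 genes of naive and recirculating T cells, all 5 lay above 50 CPM in edgeR's test, among them Satb1 (877 ± 156 CPM), S1pr1, which guides exit from the node (489 ± 54.9), and Klf2 (362 ± 101). The constant regions of the alpha and beta T cell receptor chains were read at 352 ± 55.7 CPM for Trac, 114 ± 26.3 for Trbc1 and 142 ± 34.5 for Trbc2. Trdc, the delta chain, was read at 4.97, 51.6 and 15.3 CPM in replicates 1, 2 and 3. Genes of regulatory T cells were present as well. Foxp3, their defining factor, was read at 53.8, 26.9 and 54.2 CPM, Ctla4 at 48.8, 11.8 and 58.1 CPM and Ikzf2 at 218, 127 and 202 CPM. All 6 regulatory T genes lay above 1 CPM and all 6 were lowest in replicate 2.

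The tests of thymocyte stages, mislabelling, background reads and library scaling in the following paragraphs were chosen after the result was seen. The tests on the second T cell, second erythroid, second macrophage, and second CD8, NK and CD4 lists were set before the values of those lists were looked at, though the patterns that prompted them had been seen.

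T cell genes exceeded monocyte genes in all 3 libraries, although the sort was described as a precursor population and named no T cell marker. Of 11 further T cell genes, 10 lay above 50 CPM (median 206 CPM, among them Prkcq at 486 ± 113), so mature T cells among the sorted cells are a candidate source. The c-kit requirement of the sort would remove most T cells, while neither Ly6C, which some of them carry, nor the exclusion of CD11c would. A thymocyte list, with Rag1, Ptcra, Arpp21 and Dntt among its members, had a median at most 0.0107 times that of the T cell list in any library. Thymocyte stages that use these genes are thus argued against as the main source. Stages that use them little were not tested. A mislabelled sample and a mixed sort cannot be told apart, as Kit lay at the 41.9th percentile of tested genes and no other population was analysed here for comparison. How many cells were T cells, and whether their RNA entered before or after the sort, stays open.

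Erythroid and macrophage genes were higher in replicate 1. All 10 genes of a second erythroid list were highest there, at a median of 8.99 times the mean of the others, with Slc25a37 at 283, 46.4 and 56.3 CPM and Tfrc at 209, 78.8 and 80.9 CPM. Of 10 genes of a second macrophage list, 9 were highest there, all but Pltp, at a median of 8.66 times the mean of the others, with Cd163 at 62.2, 2.996 and 9.42 CPM. The rise in replicate 1 does not by itself set these genes apart. As the median log2 shift against the others, it was 8.79-fold for the second erythroid and 8.63-fold for the second macrophage list, but also 6.70-fold for melanoma, 4.70-fold for endothelial, 4.45-fold for platelet, 3.53-fold for stromal and 2.96-fold for thymocyte genes. Of the second erythroid and macrophage lists, 5 and 6 of 10 genes exceeded the olfactory receptor background in all 3 libraries, against 0 melanoma, endothelial and stromal genes, 1 platelet gene and 1 thymocyte gene. Those counts tell of detection in every library and not of a rise in replicate 1, so they do not set the lists apart by their rise. Erythroblasts and macrophages remain a candidate source for part of the rise in that library. Olfactory receptor genes were also highest there, at a mean of 0.255 against 0.0224 and 0.0525 CPM per kilobase in replicates 2 and 3. The sort would remove most cells of both kinds, as it required Ly6C as well as c-kit, which erythroblasts carry only early on, and excluded CD11c, which some macrophages carry. More background reads are argued against as the whole cause, because the median erythroid and macrophage gene per kilobase was 32.8 times the 99th percentile of olfactory receptor genes in replicate 1. The design names no group that separates replicate 1, so beyond this mix of cells no biological explanation was tested.

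Cd8a, Cd8b1 and NK cell genes were highest and Cd4 lowest in replicate 2. A second list of 8 CD8 and NK genes shifted by a median of 1.60 log2 units in that library against the mean of the others, and 7 of its members were highest there, all but Fasl (18.4, 18.5 and 22.4 CPM). A second list of 4 CD4 genes shifted by -0.999, and 3 were lowest there, while Tnfsf8 was highest (46.4, 71.2 and 49.5 CPM). The difference of 2.59 is consistent with another mix of lymphocytes, with Ccl5 at 37.4, 279 and 102 CPM and Zbtb7b at 105, 61.8 and 115 CPM. The c-kit requirement of the sort would remove most T and NK cells. Library scaling is argued against, since 1 factor moves all genes alike, whereas Cd4 shifted by -1.51 and Cd8a by 3.93. Whether the mice, the nodes pooled or the sort differed between the experiments is not given in the sources used here, and beyond this mix of cells no biological explanation was tested.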
